A study of Homo sapiens with 5 samples.

How the data were processed

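RNA from HCT116 cells was measured on single-colour (Cy3) NimbleGen human expression arrays, 2 from control cells and 3 from SETD1A knockdown cells, grouped by the submitters' sample titles. The deposited values are linear intensity summaries per probe set; per the submitters' processing notes they were made with RMA (version not given), which corrects background, normalises arrays by quantiles and summarises probes. Each deposited array table holds 45033 probe sets, 45031 of them with 3 probes, per the file headers and columns. A deposited score column that accompanies each intensity has no stated meaning and was not used. The value table of the whole series held the same numbers as the tables of single arrays, with 0 differing values. A control entry built from 5000 random-sequence probes read 14.13 and 14.26 in control arrays and 15.25, 15.05 and 15.13 in knockdown arrays; it was left out of all tests. Image analysis settings, genome build and platform annotation are not given in the sources used here.

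Array medians were 670.2 and 670.8 (control) and 671.4, 675.2 and 666.3 (knockdown). Per the names of the deposited array tables all arrays shared 1 slide, the control arrays in the positions before the knockdown arrays, so position and group cannot be told apart. The knockdown titles carry 1 further label, C7, whose meaning as construct or clone is not explained, so effects of a construct or clone cannot be separated from those of SETD1A loss. Nothing says that arrays of a group came from separate cultures. For arrays, their number limits the precision.

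Probe sets were named by matching their RefSeq accession, without version, to a RefSeq gene table of assembly GRCh38.p14, used for names and gene order only. Of the 45033 probe sets, 18866 matched, giving 17185 genes, and 26167 stayed unnamed. For the 1349 genes with several probe sets, the probe set with the highest mean over all 5 arrays was used; in 21 of these genes different probe sets passed the threshold in opposite directions. SETD1A has 1 named probe set, and SETD1B has none named here. Genes with near-identical copies, such as histone genes, CBS and OAS or APOBEC3 family members, may share probes with them and are uncertain.

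Values were log2-transformed and fitted with limma 3.58.1 (lmFit and eBayes, no covariates, 3 residual degrees of freedom) in R 4.3.3, knockdown minus control, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Means and SDs are of linear RMA values, and folds are 2 to the power of the log2 fold. Gene lists were tested with camera (preset correlation 0.01), camera with the correlation estimated from these arrays, and fry, with adjustment over the 28 lists; counts of members are given over all genes tested and adjusted over the list alone. With the preset correlation, camera's reference distribution does not use the limited residual degrees of freedom, which enter through the statistics of single genes. The estimated version rests on 3. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.

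Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named SETD1A; AXIN2, LGR5, ASCL2, MYC and CCND1; up to 10 Wnt targets per direction by size of fold; the 12 largest rises and 12 largest falls among genes past the threshold whose arrays separate the groups and whose brighter group mean exceeds the median of all genes (811.9); and up to 4 members of lowest p in each list described. Some genes that the rule names are not reported here. A list was described where camera's adjusted p was under 0.05 or at least 20% of its members passed, and the list of cytosolic ribosomal proteins, which met neither, is given in 1 sentence. Gene symbols in the lists without a named probe set were left out of the counts.

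The fit was tested on simulated data with the 17185 genes and the spread of these arrays, 200 of them changed by known amounts and 40 others, a list, shifted by a log2 fold of 0.3. It recovered 40% of genes changed 1.25-fold, 62% of those changed 1.5-fold, 88% of those changed 2-fold and 96% of those changed 4-fold; of 159 genes called, 143 were changed genes, 11 belonged to the shifted list and 5 (3.14%) were unchanged. The shifted list gave a camera p of 9.74e-40 and an unshifted list 0.972. The simulated noise was independent between genes and few genes were changed, while 50.2% of genes passed in the real comparison. These rates and p-values check the procedure only and do not carry over to the real arrays.

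Alternatives were every probe set tested, the mean of a gene's probe sets, quantile re-normalisation, median centring, dim genes left out (mean below the median of all genes), an offset of 50 before the log, a trended robust variance, array weights, the replicate number as a block, the value table of the whole series, each array left out in turn, stricter thresholds and the other set tests.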

Results

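Transcript levels were measured on 5 single-colour NimbleGen human expression arrays hybridised with RNA from HCT116 cells, a human colorectal carcinoma line with an activating mutation in the beta-catenin gene. Control cells, labelled with the name of the pSuper vector, gave 2 arrays, and cells carrying a retroviral shRNA against SETD1A, a histone methyltransferase of the SET1 family, gave 3. Array medians lay between 666 and 675 RMA units, and the number of arrays limits the precision of every value below. The comparison addresses which genes, Wnt/beta-catenin targets among them, differ in transcript level when SETD1A is silenced.

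SETD1A itself fell 2.11-fold, from 7687 ± 275 (SD, n = 2) in control cells to 3637 ± 74.4 (SD, n = 3) in knockdown cells (log2 fold -1.08 ± 0.04 SE, adjusted p = 9.85e-05 in limma). The control arrays read 7493 and 7882, and the knockdown arrays read 3631, 3714 and 3566. Among named genes, the largest rises were in RGS5, a regulator of G-protein signalling (87.5-fold, from 152 ± 3.98 to 13321 ± 301), and TNC, the matrix glycoprotein tenascin-C (68.4-fold, from 63.7 ± 0.409 to 4361 ± 117). The deepest falls were in VIM, the intermediate filament protein vimentin (37.8-fold, from 2822 ± 19.8 to 75.1 ± 9.91), and WNT16, a Wnt ligand (31.4-fold, from 1132 ± 0.836 to 36.1 ± 3.05). Among the gene groups, interferon-stimulated genes were higher, hypoxia response, ribosome biogenesis and cholesterol synthesis genes were lower in most cases, the list of mitotic genes shifted downward with 14 of 30 members lower, and Wnt target genes moved in both directions. The shifts of the first 5 of these lists had an adjusted p = 0.171 to 0.172 with an estimated correlation.

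Of 17185 genes tested, 4133 were higher and 4498 lower in knockdown cells at adjusted p 0.05, which is 50.2% of all genes. Quantile normalisation gives all arrays like distributions, and the median log2 fold of all genes was 0.00091. A general rise or fall of transcripts could therefore not be seen, and the near-even split does not speak for or against it. At least a 1.5-fold change was seen for 1060 of the higher and 1008 of the lower genes, and at least a 2-fold change for 478 and 433. The knockdown arrays lay entirely above or below the control arrays for 69.9% of all genes, against 20% by chance with 2 arrays against 3. Arrays of the same group correlated at 0.9977 to 0.9988 across all probe sets and arrays of different groups at 0.9843 to 0.9851. The first principal component of the genes tested, which parted the groups, held 87.6% of the variance. Leaving out either control array, so that 1 remained, lowered the counts of higher and lower genes by similar amounts. All arrays shared 1 slide on which position and group cannot be told apart, and nothing in the labels says that arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

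**Figure D1:**
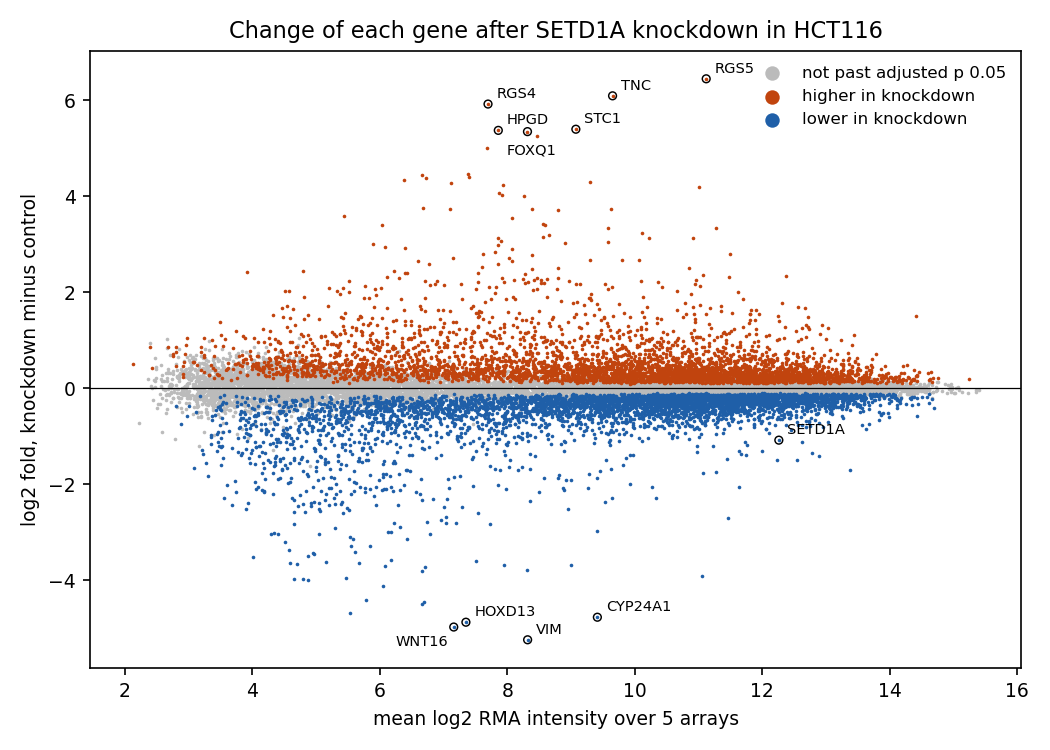
Change of each of the 17185 genes against its brightness. The x axis is the mean log2 RMA intensity over the 5 arrays, the y axis is the log2 fold (knockdown minus control), each point is a gene, and coloured points passed adjusted p 0.05; SETD1A lies at -1.08, RGS5 at 6.45 and VIM at -5.24.

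Other genes with large rises included the G-protein regulator RGS4 (from 17.7 ± 0.605 to 1078 ± 130), the secreted hormone STC1 (42.2-fold), the prostaglandin-degrading enzyme HPGD (41.5-fold), the forkhead factor FOXQ1 (40.8-fold) and the secreted epithelial protein BPIFB1 (38.1-fold). The fibrillar collagen COL3A1 rose 19.8-fold and the growth factor binding protein IGFBP3 18.4-fold, the last from 360 ± 5.48 to 6633 ± 93.6. The amino acid transporter SLC6A20 rose 16-fold and the zinc finger factor GLIS3 13.4-fold. Large falls included the homeobox gene HOXD13 (29.3-fold), the vitamin D hydroxylase CYP24A1 (27.3-fold, from 4956 ± 58.4 to 182 ± 10.5), the fatty acid activating enzyme ACSL5 (15.1-fold, from 10834 ± 811 to 716 ± 38.7) and the dipeptidase DPEP1 (13.9-fold). CBS, an enzyme of cysteine synthesis whose probes may also read a near-identical gene copy, fell 12.9-fold, and the Notch target HEY1 fell 12.8-fold. ENC1 fell 7.82-fold, the metalloprotease ADAM19 6.51-fold and the kinase inhibitor PKIB 5.71-fold. HNF4A, a transcription factor of intestinal and liver epithelium, fell 5.18-fold from 1988 ± 55.8 to 384 ± 13.6. These genes, RGS5, TNC, VIM and WNT16 included, had adjusted p between 3.46e-06 and 0.000122. The dimmer group mean of RGS4, HPGD, FOXQ1, WNT16, BPIFB1 and HOXD13 was under 50 RMA units, as it was for LEF1, MMP7, CDH2, COL5A1, LYZ and VWF below. That is near enough to the random-sequence probes (14.13 to 15.25) that the size of those folds is imprecise.

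The Wnt/beta-catenin target list held 49 measured genes, of which 21 rose, 15 fell and 13 did not pass the test. When adjusted over the list alone, 21 were higher and 17 lower. AXIN2, a negative feedback regulator of the pathway, rose 1.35-fold from 4592 ± 325 to 6179 ± 102 (log2 fold 0.43 ± 0.05 SE, adjusted p = 0.00304). CCND1, which encodes cyclin D1, rose 1.51-fold from 7698 ± 347 to 11585 ± 157 (0.59 ± 0.04, adjusted p = 0.00058). MYC fell 1.47-fold from 18732 ± 184 to 12745 ± 252 (-0.56 ± 0.04, adjusted p = 0.000416). The stem cell receptor LGR5 read 36.5 ± 1.09 and 39.3 ± 1.1 (adjusted p = 0.101), and the stem cell factor ASCL2 read 52.1 ± 0.806 and 46.8 ± 2.93 (adjusted p = 0.0978). Both lay below the lower quartile of all genes (76.93), and LGR5 passed the threshold after quantile re-normalisation (adjusted p = 0.0402).

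The strongest rises among Wnt targets were in NEDD9, a focal adhesion scaffold (5.31-fold, from 68.8 ± 2.88 to 365 ± 9.81, with a log2 fold of 1.12 in its second, dimmer probe set), the growth factor FGF18 (4.73-fold, from 431 ± 16.5 to 2041 ± 23.8) and the transcription factor SP5 (4.17-fold). The secreted Wnt antagonists DKK1 (2.84-fold, from 11612 ± 272 to 33002 ± 323) and NOTUM (2.68-fold, from 2101 ± 99.6 to 5637 ± 213) rose as well. L1CAM, EPHB3, TNS4 and CLDN1 rose between 1.93-fold and 2-fold, and SMOC2 rose from 13.2 ± 1.62 to 25.2 ± 1.42. LEF1, a nuclear partner of beta-catenin, fell from 319 ± 16 to 27.2 ± 5.02, and RNF43, a ubiquitin ligase that removes Wnt receptors, fell 2.82-fold from 11126 ± 383 to 3940 ± 96. The protease MMP7 fell 2.73-fold, TIAM1 1.6-fold and FOSL1 1.58-fold. Near or below the level of the random-sequence probes, PROX1 fell from 28 ± 3.27 to 7.25 ± 2.51, CCN4 from 62.9 ± 0.724 to 18.3 ± 5.83 and NRCAM from 16.3 ± 1.66 to 8.43 ± 1.3, so their folds and that of SMOC2 are not given. The list as a whole did not shift against other genes in camera (median log2 fold 0.08, mean 0.02, adjusted p = 0.241, and adjusted p = 0.481 with an estimated correlation). The rotation test fry asks whether the members moved on balance in one direction and makes no comparison with other genes. It gave an adjusted p = 0.000459 upward. Fry passed 26 of the 28 lists, so this value does not set the Wnt list apart.

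**Figure D2:**
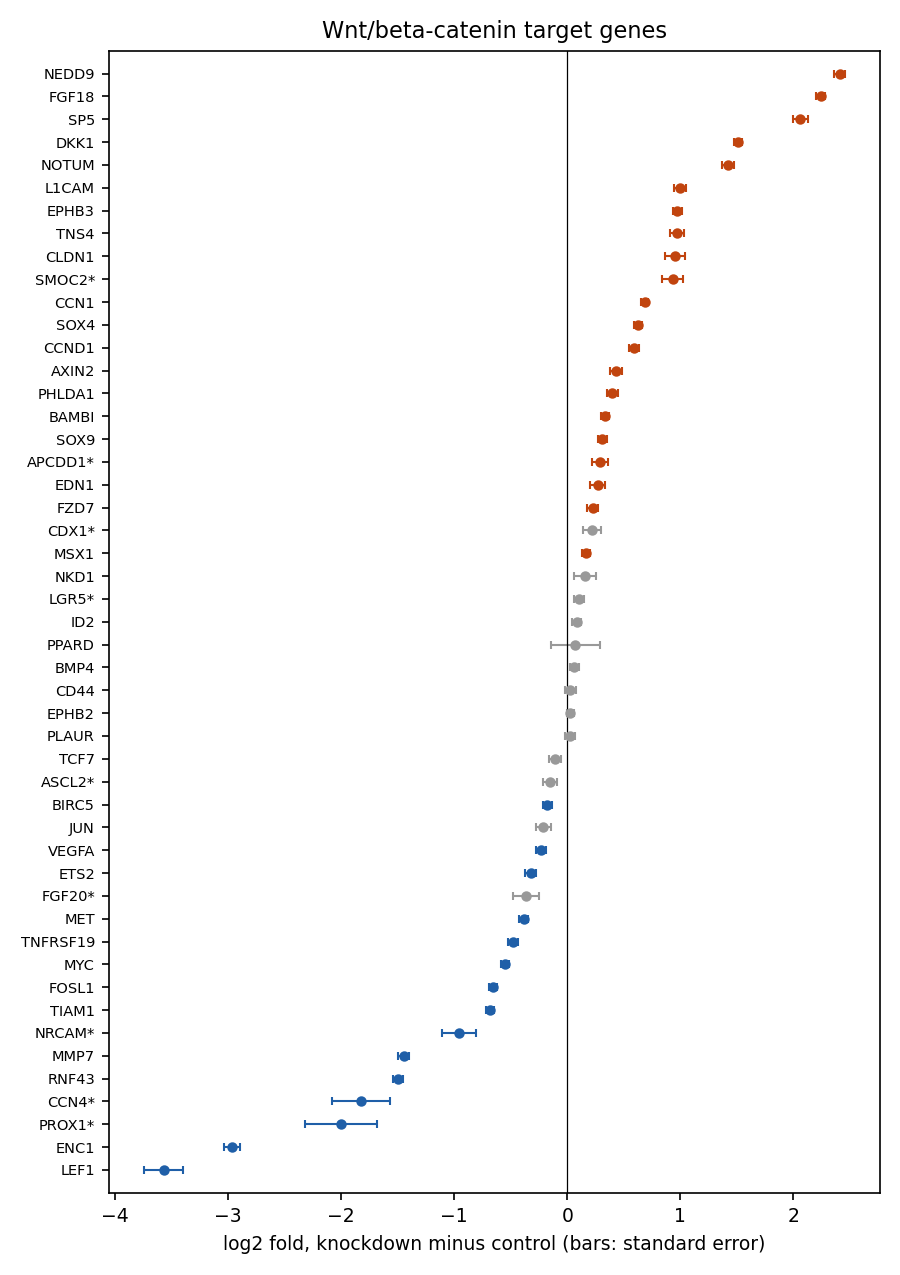
Log2 fold (knockdown minus control, x axis) of the 49 measured Wnt/beta-catenin target genes, with bars for the standard error of the limma fit. Red points rose, blue points fell and grey points did not pass adjusted p 0.05, and an asterisk marks genes below the lower quartile of all genes; values run from LEF1 at -3.57 to NEDD9 at 2.41.

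The shorter list of 12 pathway feedback targets is a subset of the Wnt target list. In it 5 rose and 3 fell, the same numbers adjusted over the list alone, with DKK1, SP5 and NOTUM up and RNF43 and LEF1 down (camera adjusted p = 0.447). Of 31 pathway components, 14 rose and 6 fell, again the same adjusted over the list alone (camera adjusted p = 0.133). The ligand WNT5B rose 1.83-fold, the dim ligand WNT5A fell from 46.9 ± 0.718 to 16.7 ± 2.25 and the receptor FZD8 fell 1.64-fold. TCF7L2, the main intestinal partner of beta-catenin, fell 1.72-fold from 9489 ± 196 to 5531 ± 208 (adjusted p = 0.000337).

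Among 17 measured subunits of SET1/MLL complexes, 1 rose and 5 fell, as many as adjusted over the list alone (camera adjusted p = 0.166). Besides SETD1A, PAXIP1 fell 1.45-fold from 2630 ± 62.3 to 1811 ± 5.65, PAGR1, its partner in the MLL3/MLL4 complexes, fell 1.17-fold and HCFC1 fell 1.16-fold. PAGR1 no longer passed the threshold without the first control array (adjusted p = 0.0549), nor HCFC1 without the second (adjusted p = 0.0612).

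Of 28 gene lists, 11 shifted in camera with its preset correlation. None of the 28 held when the correlation was estimated from these arrays (lowest adjusted p = 0.171, with 6 lists at an unadjusted p under 0.05). That test rests on 3 residual degrees of freedom, and fry gave an adjusted p under 0.05 for 26 lists. Interferon-stimulated genes stood out upward: 22 of 26 rose, both over all genes and adjusted over the list alone, and all 26 folds were positive. The list had a median log2 fold of 0.53 (adjusted p = 2.9e-10, and adjusted p = 0.171 with an estimated correlation). OAS1, an antiviral RNA sensor, rose 7.17-fold from 68.6 ± 0.133 to 492 ± 5.28, IFIT3 rose 4.94-fold from 170 ± 1.78 to 841 ± 29.1, IFIT2 rose 4.58-fold and IFI6 rose 3.25-fold. The knockdown arrays carry 1 construct or clone label, so the response of this list was read for that label alone.

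Epithelial genes also shifted upward, with 13 of 29 higher and 2 lower (15 and 2 adjusted over the list alone; median 0.17, adjusted p = 0.00485, and adjusted p = 0.174 with an estimated correlation). The epithelial transcription factor EHF rose 2.4-fold from 4960 ± 175 to 11907 ± 129, the mucin MUC1 rose 2.79-fold and CDH1, which encodes E-cadherin, rose 1.34-fold from 4891 ± 72.1 to 6570 ± 46.3. In the same arrays embryonic kidney line markers were lower in 11 of 15 cases (median -1.05), and VIM and CDH2 fell 37.8-fold and 6.93-fold. Replication-dependent histone genes were higher in 17 of 46 cases and lower in 2, equally so adjusted over the list alone (median 0.10, adjusted p = 0.00492, and adjusted p = 0.481 with an estimated correlation). H2BC21 rose 2.98-fold, H3C10 1.44-fold and H3C8 1.34-fold, while H4C4 fell 1.27-fold. Probes of these genes may read near-identical copies, so each value is uncertain.

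Genes of glycolysis and the hypoxia response fell, 21 of 30 being lower and 3 higher (22 and 3 adjusted over the list alone; median -0.41, adjusted p = 2.56e-05, and adjusted p = 0.171 with an estimated correlation). CA9, a carbonic anhydrase induced by hypoxia, fell from 367 ± 11.7 to 21.1 ± 1.49, near the random-sequence probes, ANKRD37 fell 3.29-fold, NDRG1 fell 2.55-fold from 12304 ± 53.1 to 4817 ± 77.8 and the hexokinase HK2 fell 2.14-fold. Ribosome biogenesis genes linked to MYC fell by smaller amounts, 25 of 29 being lower and the others not passing (27 lower adjusted over the list alone; median -0.26, adjusted p = 5.12e-06, and adjusted p = 0.172 with an estimated correlation). Their clearest members were NOP16 (1.32-fold lower), WDR12 (1.28-fold), TCOF1 (1.28-fold) and HSPE1 (1.34-fold). Cytosolic ribosomal protein genes held few calls, with 1 of 30 higher and 3 lower (1 higher adjusted over the list alone; adjusted p = 0.241). Cholesterol synthesis genes were lower in 18 of 25 cases and higher in 1, also adjusted over the list alone (median -0.22, adjusted p = 0.000141, and adjusted p = 0.171 with an estimated correlation). MSMO1 fell 1.73-fold, HMGCS1 1.57-fold from 3889 ± 83.1 to 2482 ± 29.7, IDI1 1.51-fold and the sterol-regulated INSIG1 1.46-fold.

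Lists of cell cycle and repair genes had small shifts downward in camera with its preset correlation, and many of their members did not pass. In the list of G2/M and mitosis genes 14 of 30 were lower and the others did not pass (13 lower adjusted over the list alone; median -0.14, adjusted p = 0.000141, and adjusted p = 0.172 with an estimated correlation). HMMR fell 1.82-fold, PTTG1 1.56-fold, CENPF 1.29-fold and BUB1 1.24-fold. Among G1/S and replication genes 13 of 29 were lower, also adjusted over the list alone (median -0.12, adjusted p = 0.00717, and adjusted p = 0.441 with an estimated correlation). POLE2 fell 1.41-fold, and UHRF1, MCM5 and GINS1 fell between 1.18-fold and 1.21-fold. DNA repair genes showed 18 of 30 lower and 1 higher (20 and 2 adjusted over the list alone; median -0.17, adjusted p = 0.00304, and adjusted p = 0.212 with an estimated correlation). POLQ fell 1.54-fold, BRCA1 1.39-fold, BRCA2 1.38-fold and ATR 1.22-fold. Oxidative phosphorylation genes were lower in 15 of 29 cases and higher in 1 (16 and 1 adjusted over the list alone; median -0.16, adjusted p = 0.00177, and adjusted p = 0.442 with an estimated correlation). The complex I subunits NDUFB10 and NDUFB5 both fell 1.24-fold (NDUFB8 had a log2 fold of -0.32), and NDUFS1 of the same complex rose 1.26-fold.

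Several lists held large changes in both directions and did not shift against other genes in camera. Fry, which makes no such comparison, gave adjusted p = 0.000196 for mesenchymal, 0.00493 for HOX and 0.000432 for intestinal stem cell genes. For intestinal differentiation genes fry gave an adjusted p = 0.218. Of 24 mesenchymal genes 6 rose and 11 fell (6 and 12 adjusted over the list alone; median -0.22, adjusted p = 0.241). TNC and SPARC, both matrix proteins, rose 68.4-fold and 6.04-fold, while VIM and the neural cadherin CDH2 fell 37.8-fold and 6.93-fold. Of 38 HOX genes 15 rose and 11 fell (16 and 12 adjusted over the list alone), and the median of 0.12 and the upward camera test (adjusted p = 0.299) differed in sign from the mean of -0.14. HOXA13 rose 2.55-fold and HOXB4 2.02-fold, HOXD13 fell 29.3-fold, and HOXD10 fell from 201 ± 7.54 to 18.9 ± 1.49. These falls stood beside those of embryonic kidney line markers (median -1.05). Intestinal differentiation genes split into 8 higher and 7 lower of 30, likewise adjusted over the list alone (adjusted p = 0.648). The peptidase DPP4 rose 3.2-fold from 3232 ± 156 to 10333 ± 181 and the dim TFF1 rose from 12.6 ± 0.84 to 39.7 ± 5.69, and HNF4A and the carbonic anhydrase CA2 fell 5.18-fold and 1.75-fold. Intestinal stem cell genes gave 8 higher and 5 lower of 19, the same adjusted over the list alone (adjusted p = 0.353). EPHB3 and ALCAM rose 1.96-fold and 1.43-fold, and RNF43 and CDCA7 fell 2.82-fold and 1.56-fold.

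Among p53 targets 13 of 28 rose and 6 fell (15 and 6 adjusted over the list alone; adjusted p = 0.0849). TP53INP1 rose 2.6-fold, TP53I3 2.21-fold and GADD45A 1.31-fold, and the apoptosis inducer PMAIP1 fell 1.65-fold. Apoptosis regulators gave 15 higher and 7 lower of 29 (15 and 8 adjusted over the list alone; adjusted p = 0.126). The death-promoting BMF rose 1.95-fold, and the survival genes BCL2L1 and CFLAR rose 1.5-fold and 1.32-fold. For NF-kB targets 10 of 30 were higher and 5 lower (10 and 6 adjusted over the list alone; adjusted p = 0.238). The inhibitor NFKBIA rose 1.84-fold, TNFAIP2 1.65-fold and the dim chemokine CCL2 from 15.5 ± 0.412 to 65.9 ± 1, and TRAF1 fell 1.67-fold. Stress response genes gave 8 higher and 13 lower of 29 (9 and 13 adjusted over the list alone; adjusted p = 0.299). ASNS fell 2.3-fold, STC2 1.91-fold, ATF3 1.73-fold and SLC7A11 1.52-fold, all of them targets of the integrated stress response. Of 25 housekeeping genes 4 rose and 7 fell, as they did adjusted over the list alone (adjusted p = 0.241). HPRT1 and GPI fell 1.34-fold and 1.26-fold and GUSB rose 1.29-fold.

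Markers of other cell types were read as a check of what the cultures held. Embryonic kidney line markers, a proxy for virus packaging cells, were lower in 11 of 15 cases and higher in 2, also adjusted over the list alone (median -1.05, adjusted p = 0.00177, and adjusted p = 0.212 with an estimated correlation), alongside the falls of VIM, CDH2 and the HOXD genes. HOXD11 is in both the kidney and the HOX list. Large falls were not limited to these genes, as ACSL5, CYP24A1 and DPEP1 also fell. LIN28B, a repressor of let-7 microRNAs, fell from 342 ± 17 to 16.6 ± 4.55, where the size of the fold is imprecise, ZIC2 fell 2.62-fold from 1785 ± 8.62 to 681 ± 16.3, SIX2 fell 2.07-fold and TBX2 2.02-fold. Fibroblast markers gave 2 higher and 2 lower of 14, likewise adjusted over the list alone (adjusted p = 0.444). COL3A1 rose 19.8-fold and the dim PDGFRA from 21.2 ± 1.31 to 32.6 ± 1.57, and COL5A1 and THY1 fell 3.7-fold and 1.36-fold. Leukocyte markers gave 2 higher and 7 lower of 15, unchanged adjusted over the list alone (adjusted p = 0.238). LYZ rose 6.01-fold from 37.1 ± 2.98 to 227 ± 54.6 and HLA-DRA 2.72-fold, and CD68 fell 1.97-fold. Endothelial markers gave 3 higher and 3 lower of 10, also adjusted over the list alone (adjusted p = 0.744; median -0.01, mean 0.20, test upward). PECAM1 rose from 15.5 ± 1.92 to 42.2 ± 2.16 and VWF 2.49-fold, both at low intensity, and EGFL7 and ESAM fell 1.21-fold and 1.19-fold.

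**Figure D3:**
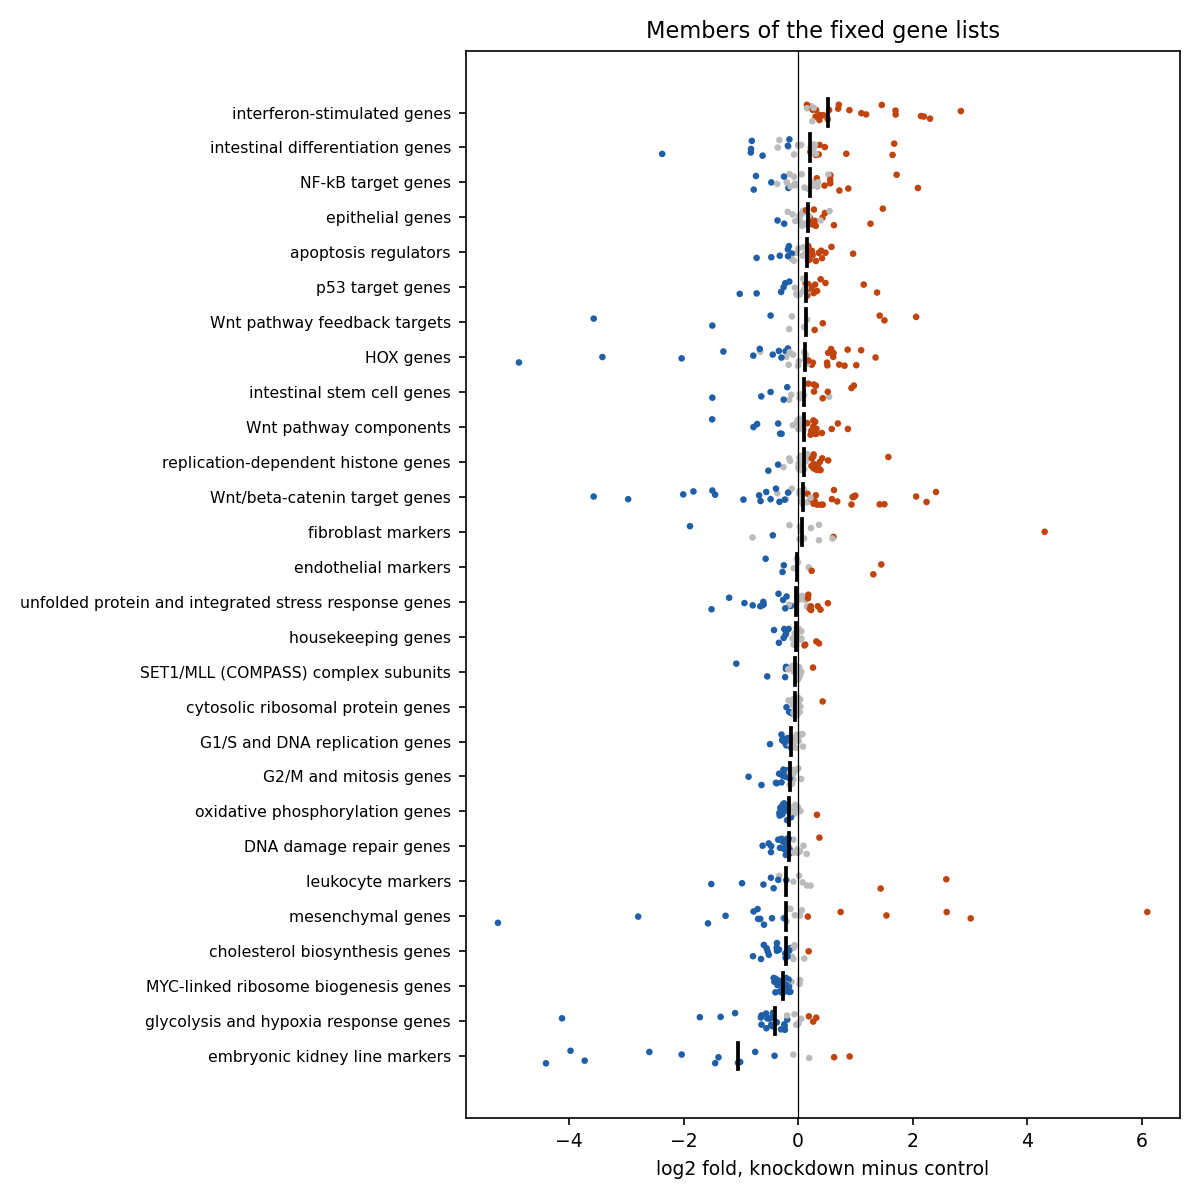
Log2 fold (knockdown minus control, x axis) of every measured member of the 28 gene lists, ordered by the list's median (black bar). Points are genes, red for rises, blue for falls and grey for genes that did not pass adjusted p 0.05; list medians run from -1.05 for embryonic kidney line markers to 0.53 for interferon-stimulated genes.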

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

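Probe sets without a gene name here lie outside the comparison of the report and were fitted with the same model together with the named probe sets. Of 26167 such probe sets, 11624 passed adjusted p 0.05, with 4990 higher and 6634 lower in knockdown than in control arrays, and 6305 of them had a brighter group mean above the median of the named genes. The largest rises among them were in BC029044, from 39.9 ± 0.501 (SD, n = 2) to 4925 ± 178 (SD, n = 3), and BC069462, from 12.6 ± 0.834 to 1053 ± 18.1. The deepest falls were in BC030573, from 2840 ± 107 to 94.5 ± 11.7, and AF060152, from 2174 ± 101 to 16 ± 2.94. These 4 were picked after their values were seen, by size of change, and their genes were not named here.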

How the results depend on the processing

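All alternatives were planned before the data were examined. Across 15 settings the direction of SETD1A and its side of the threshold stayed (log2 fold -1.12 to -1.04). So did those of all but 3 of 138 results for named genes in the settings where each gene was tested. Genes below the brightness limit were not tested with dim genes left out. Most named genes were picked from these arrays for a large fold or low p, so few could lose their call. The value table of the whole series held the same numbers, so that setting could not differ. LGR5 gained a call under quantile re-normalisation, and PAGR1 and HCFC1 each lost theirs without a control array (first and second); their adjusted p ran over 0.0402 to 0.532, 0.000158 to 0.0549 and 0.000126 to 0.0612. Testing every probe set gave 9398 higher and 11481 lower, since more features were tested; adjusted p 0.01 gave 2670 and 2831, and a 1.5-fold minimum 1060 and 1008. Leaving out an array gave 2956 (without the second control array) to 4340 lower genes and 47.6% to 49.6% of calls higher, against 45% with every probe set; a lone control array is assumed to vary like the knockdown arrays, and fewer arrays leave fewer residual degrees of freedom. The labels do not say whether the replicate numbers pair the arrays. Deviations from the group means correlated weakly in the only pairs (0.0055 and 0.086), which does not settle it. The deviations of the control arrays mirror each other, so these values are not separate checks. With the number as a replicate block, 7165 genes passed, 6675 of them shared with the 8631, and 49.3% were higher. The Wnt list passed under fry (median 0.082, adjusted p = 0.000459), which tests another question and passed 26 of the 28 lists. The Wnt list passed in no other setting (adjusted p 0.0998 to 0.481). Of the 11 lists called by camera, 0 were called with an estimated correlation (6 at unadjusted p under 0.05). With dim genes left out the medians of 2 uncalled lists turned sign, mesenchymal genes (0.066) and intestinal differentiation genes (-0.48), while for endothelial markers (-0.26) the median was already -0.01 and only the direction of the test turned; 7, 4 and 2 members remained. With every probe set the test of intestinal differentiation genes turned downward (median 0.053); the cause was not tested further. With dim genes left out the HOX list and apoptosis regulators gained a call (adjusted p = 6.03e-06 and 0.049), and both had an adjusted p = 0.481 with an estimated correlation. That filter left 17 of 38 HOX genes, 8 of 10 in HOXB and 0 of 9 in HOXD. It uses the mean over all arrays and so removed HOXD13, which was bright in control arrays (1239) and fell. Others, such as HOXD10 (201 in control arrays), lay under the brightness limit in both groups. The gain is not evidence of an upward shift. Signal over background limits the folds of genes near the random-sequence probes.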

Other observations

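The tests of dim interferon probe sets and of DNA gain and loss beside the HOX clusters, in the form given here, and those of the shRNA vector, of packaging cells, of shared HOX probes and of neighbouring genes were chosen after the results were seen, and the genes named in this part were chosen after their values were seen.

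The HOX clusters moved in different directions. In HOXB, 8 of 10 measured genes rose, none of the others passing, with a median log2 fold of 0.62: HOXB8 rose by 1.10, HOXB7 by 0.86, HOXB3 by 0.72 and HOXB13 by 0.51. All 9 measured HOXD genes fell, with a median of -0.78; 3 of them were dim in both groups, and the falls ran from -0.29 in HOXD3 to -4.87 in HOXD13, with HOXD11 at -2.03 and HOXD8 at -1.30. HOXA (4 higher and 1 lower of 10, median 0.15) and HOXC (3 higher and 1 lower of 9, median -0.09) were mixed.

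The APOBEC3 cytidine deaminases, which restrict retroviruses and lie side by side in the genome, rose in all 7 measured members. APOBEC3G rose most, from 618 to 6227 RMA units (log2 fold 3.33 ± 0.04 SE, adjusted p = 6.91e-06), followed by APOBEC3H (2.29 ± 0.05), APOBEC3F (1.31 ± 0.05), APOBEC3C (1.28 ± 0.05), APOBEC3D (1.23 ± 0.08), APOBEC3B (1.06 ± 0.05) and APOBEC3A (0.82 ± 0.09). The members are similar in sequence, and probes shared between them were not examined.

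The rise of interferon-stimulated genes was set against technical causes. Dim probe sets are argued against for the 9 members whose control mean exceeded the median of all genes. Of these, 100% were higher past the threshold, against 24.6% of all genes chosen in that way. OAS1, IFIT3, IFIT2 and IFI6 were not among the 9. With an offset of 50, 88.5% of the 26 members were higher. That setting cannot decide, since calls over all genes also rose with it (4462 higher and 4942 lower, against 4133 and 4498). An earlier rule, written before the data were examined, covered dim probe sets and scaling together and would have argued against both. Under quantile re-normalisation and under median centring, 84.6% of the 26 members were higher. That cannot decide on scaling, since the deposited values were already normalised by quantiles and a further normalisation moved little. A response to the shRNA vector instead of to loss of SETD1A cannot be told apart, because the knockdown labels name 1 construct or clone and do not say whether the control vector expressed an shRNA. Loss of SETD1A stays open as the biological explanation, untested beyond this comparison.

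The lower embryonic kidney line markers may reflect packaging-type cells in the control arrays, or a difference between the HCT116 populations themselves. Of the 13 markers past the threshold, 15.4% were higher in knockdown cells (LHX1, 91.9 to 172, and PAX2, 233 to 362), which such cells alone would not give, while the others were lower, so this explanation cannot be told apart. The brightest markers in control cells were ZIC2 at 1785, NEFL at 493, SIX2 at 362 and LIN28B at 342 RMA units, and 7 of the 15 stood above the lower quartile of genes in the knockdown arrays as well; 1 marker is also in the HOX list. The abundant transcripts of a kidney line were not analysed here, and loss of SETD1A stays open.

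For the opposite shifts of HOXB and HOXD, probes shared between paralogs cannot be told apart: 83.3% of the 6 paralog pairs (5 of 6) moved in opposite directions, but that follows from the shifts themselves. A gain of DNA reaching the genes beside HOXB cannot be told apart either. The 10 bright genes flanking HOXB had a median log2 fold of 0.101, with the inner 8 between -0.01 and 0.70, a spread that holds the cluster's 0.62; an earlier rule, on the flank medians alone and written before that test, would have argued against it. A loss of DNA spanning all 10 genes flanking HOXD is argued against only by their median of 0.077. The inner 8 lay between -0.55 and 0.18, all above the cluster's -0.78, but flanks lowered less than the cluster would also have met this rule. The rule differed from that for HOXB, which set a fixed limit on the flanks. Under a like limit, the -0.55 would have left HOXD undecided too, so the 2 verdicts differ through their rules. A loss reaching only some flanking genes was not excluded. CDCA7 (-0.64), OSBPL6 (-0.55) and MTX2 (-0.36) were lower past the threshold, while ATF2 (0.18), LNPK (0.14) and AGPS (0.19) were higher. A loss limited to HOXD was not tested. A clone-specific state and loss of SETD1A both stay open.

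A further hypothesis was that Wnt targets changed more often than other genes of like brightness, in either direction. Of the 49 targets 73.5% passed the threshold, against a median of 49% and a central range of 34.7% to 61.2% in 10000 random lists matched on brightness, and 99.99% of those lists had a smaller share. The median size of the log2 fold was 0.43, against 0.18 (0.12 to 0.25) in random lists. This goes with an enrichment of changed genes in the list against random lists. Camera found no common direction against other genes (adjusted p = 0.241). Fry gave an adjusted p = 0.000459 upward, but it passed 26 of the 28 lists and so does not set this list apart. A high share was not particular to Wnt targets. It was 86.2% for MYC-linked ribosome biogenesis genes, 80% for glycolysis and hypoxia response genes and 75.9% for apoptosis regulators. Some other lists had smaller shares, down to 13.3% for cytosolic ribosomal proteins. The random draws treat genes as independent, so 99.99% may overstate the evidence. Differences between the lists were not tested. Of the feedback targets 66.7% passed, with 82.42% of random lists smaller, and their median fold size was 0.46 against 0.19, with 99.73% of random lists smaller. All 12 feedback targets are also in the Wnt target list, so these values are not separate evidence. For pathway components the share was 64.5%, with 79.7% smaller, and the fold size 0.27 against 0.18, with 96.58% smaller.

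Another hypothesis was that neighbouring genes changed together along chromosomes. Across 15444 adjacent pairs without a shared symbol stem, Spearman's rho between their log2 folds was 0.123, against a highest value of 0.032 over 10000 shuffled orders (permutation p = 1e-04, the smallest these can give). The relation is across genes, which are not independent replicates, and is consistent with a weak regional component; probe design and copy number were not examined.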
